A study of Mus musculus with 2 samples.

How the data were processed

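Libraries of spleen cells were compared, 1 from mice given saline and 1 from mice given Plasmodium chabaudi chabaudi AS. Per the labels' protocols, spleens were passed through a strainer, red cells were lysed, propidium iodide-negative live cells were sorted and libraries were made with a 10x Genomics 3′ kit. The deposited values are raw UMI counts per gene and cell barcode, per the file headers and as the whole-number values show. Per the submitters' processing notes, Cell Ranger 3.1.0 made them against the mouse build mm10; the annotation release is not given in the sources used here. The features are 32285 mouse genes and 1 added feature named GFP, which was kept out of every comparison. No deposited column was left unused for its unit. Of the genes of the interferon-stimulated list, 28 of 30 are in the features used here.

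The choices for filters, markers, gene lists, named genes and most alternatives were fixed before the data were examined, unless stated otherwise. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. In the saline library 469 barcodes had too few genes and 661 too many mitochondrial UMIs, and in the infected library 269 and 424; 11069 and 4573 passed. Scrublet (scanpy 1.11.5), run per library with an expected rate of 0.06, called 490 saline barcodes (4.43%) and 34 infected barcodes (0.743%) doublets, which were removed. The score threshold that Scrublet set itself was 0.219 in saline and 0.322 in infected, so removal may have been less strict in the infected library. No alternative removed more barcodes as doublets. Kept cells had medians of 1220 and 1846 genes. Over all barcodes, haemoglobin took 9.08% of saline and 1.09% of infected UMIs, and immunoglobulin 1.66% and 5.83%.

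Both libraries were clustered together with no integration: log-normalized counts, 2000 variable genes without response, immunoglobulin, T cell receptor, ribosomal, mitochondrial, haemoglobin, Xist and Y-linked genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Clusters carry the prefix C, and sub-clusters of T-like and NK-like cells the prefix T. Fixed marker lists of 19 classes named each cluster by its mean marker z score, with at least 3 markers seen in at least 10% of its cells and a gap of at least 0.2 to the next class. Sub-clusters were named by the share of cells with a UMI of lineage genes: Cd4 or Cd8b1 in at least 30% of cells and 5 times as often as the other, Foxp3 in at least 10% for Treg-like cells, and Ncr1 in at least 10% with Cd3e in under 30% for NK-like cells. Gamma delta T-like sub-clusters had Cd4 and Cd8b1 each in under 30% of cells and at least 3 of their class's markers in at least 10%. Sub-clusters with Cd4 and Cd8b1 each in at least 10% of cells were clustered once more. These thresholds and this last step were chosen after the clusters had been seen. A class was to be compared only if none of its clusters had more markers of another class than of its own among its 10 leading genes. T6.0 and T6.3 break this rule with Treg-like markers and were kept as CD4 T-like after the result was seen, since regulatory T cells are themselves CD4 T cells; log2 ratios, medians and counts without them stand in square brackets beside those with them where they could be measured. Some named genes, such as Fcer2a, Cr2, Slc40a1, Vcam1, Hmox1, Spic and S100a8, are also markers of their class, and cells that lack them are less likely to be in it.

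For each class with at least 100 cells per library, UMIs were summed per library and scaled to CPM by the class total, and the log2 ratio of infected over saline was taken for genes with at least 30 UMIs. Classes with at least 50 cells were added after the data were seen. A library with 0 UMIs was set to 3 counts, which gives a bound that leaves out counting error in the other library; a share of 0 cells is given with the upper limit of 3 cells. With 1 library per group no test was run. Genes at least 2-fold apart are counted as a description of these 2 libraries. Of 21 fixed gene lists, each tied to stated classes, the median log2 ratio is given with its percentile among 10000 random lists of the same size drawn within 20 bins of expression. Aldoa, whose symbol names 2 features, was left out of the glycolysis list. For lead genes, each cell was thinned to 1000 UMIs and shallower cells were left out.

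Genes were named per class by 3 parts of a fixed rule. The first takes the 8 highest and 8 lowest log2 ratios among genes with at least 50 UMIs and 100 CPM in the higher library and a class CPM there of at least 0.5 of the CPM over all kept cells, without predicted models, receptor segments and ribosomal, mitochondrial and haemoglobin genes. The second takes the 2 highest, the 2 lowest and the most abundant member of each list, of which 2 to 4 are named. The third takes a fixed set of lead genes per class. Some genes that the rule picks are not reported here.

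On simulated counts with 200 altered genes per class, 97.0% of genes with a true 3-fold difference were at least 2-fold apart in B-like cells (of 11037 genes), 98.5% in CD4 T-like (9101), CD8 T-like (8706) and erythroid-like cells (9201) and 92.4% in red pulp macrophage-like cells (4848). At 6-fold all were. At 1.5-fold the shares were 2.99%, 5.97%, 10.8%, 2.99% and 10.8%, and among unaltered genes 0.249%, 0.427%, 0.670%, 0.522% and 1.38%; none lay on the wrong side. Of 200 lists of 15 unaltered genes, 2.5%, 7.0%, 5.5%, 3.5% and 4.0% fell outside the middle 95% of random lists, and all 50 lists of raised genes reached percentile 100. The counts were drawn with counting error only, around 1 profile shared by both libraries. They held no variation between animals or libraries and no difference in cluster mix. A shift of most genes, as in erythroid-like cells, was not simulated either. These shares therefore give no rate of false calls for the real data.

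The alternatives fixed at the start kept called doublets, used a minimum of 1000 UMIs or at most 5% mitochondrial UMIs per cell, Leiden resolution 2, all genes as variable genes, separate clustering of the libraries, edgeR (4.0.16) TMM factors, a CPM total without haemoglobin, immunoglobulin, mitochondrial and ribosomal genes, equal weight per cell, thinning of the deeper library, and at least 10 or 100 UMIs per gene, and left erythroid-like cells out of the denominator of shares. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3, and coordinates come from GENCODE M21.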

Results

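Spleen cells of C57BL/6J mice were profiled by single-cell RNA sequencing with 3′-end capture, 1 library per group. The infected mice had received red blood cells carrying Plasmodium chabaudi chabaudi AS, a rodent malaria parasite, and their spleens were taken at day 7. The control mice had received saline, and their library carries day 0 in its title. The saline library held 12170 barcodes and 45771165 UMIs (unique molecular identifiers, each marking 1 captured RNA molecule), with a median of 3082 UMIs per barcode. The infected library held 5055 barcodes and 52184015 UMIs, with a median of 5503. After filtering, 10579 saline and 4539 infected cells were kept, with medians of 3059 and 5823 UMIs. There were no replicate libraries and the labels do not state how many animals each library pools, so no difference between the groups was tested and every value describes these 2 libraries. Intervals in parentheses are exact 95% intervals and cover counting error only. Xist, the RNA that coats the inactive X chromosome, stood at 1286 CPM (counts scaled to the same total in each library) in saline and 848 CPM in infected cells, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 or 1 UMI in either library.

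The first comparison asked how the cell types of the spleen differed between infected and saline mice. Plasma-like cells, which secrete antibody, made up 0.369% (0.262 to 0.504) of saline and 8.24% (7.46 to 9.08) of infected cells, a 22.4-fold higher share (12.5-fold with a 5% mitochondrial limit and 6.35-fold with each library clustered on its own). Monocyte-like cells, circulating phagocytes that enter inflamed tissue, made up 0.700% (0.550 to 0.877) and 2.95% (2.48 to 3.49), 4.22-fold higher. Of these infected cells 133 of 134 lay in C24, a cluster named narrowly over red pulp macrophage-like cells. Natural killer (NK)-like cells stood at 2.49% (2.20 to 2.80) and 0.705% (0.483 to 0.994), 3.53-fold lower (8.97-fold with the 5% limit), and gamma delta T-like cells at 1.94% and 0.617%, 3.14-fold lower (1.43-fold with the 5% limit and 1.92-fold with all genes eligible as variable genes). Cluster T11 held 131 of the 205 saline and 27 of the 28 infected gamma delta T-like cells. Its 10 leading genes held only 1 marker of that class, so its name is weak. CD8 T-like cells, the cytotoxic T lineage, stood at 11.9% (11.3 to 12.5) and 7.16% (6.43 to 7.95), 1.66-fold lower. This was 1.19-fold with the 5% limit and 1.45-fold with resolution 2 or all genes variable. CD4 T-like cells, the helper lineage, stood at 13.2% (12.6 to 13.9) and 13.1% (12.1 to 14.1). The infected CD4 T-like share includes T6.0 (1.85% of infected cells) and T6.3 (0.727%), which held no saline cells and whose naming is uncertain.

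B-like cells were the most abundant class in both libraries, with 51.7% (50.7 to 52.7) of saline and 45.5% (44.0 to 46.9) of infected cells. Red pulp macrophage-like cells, which clear aged red cells and recycle their iron, made up 2.92% and 4.65%, and erythroid-like cells, the precursors of red cells, 6.05% and 7.38%. Neutrophil-like cells made up 0.889% and 1.56%, type 1 dendritic (cDC1)-like cells 0.785% and 1.28%, type 2 dendritic (cDC2)-like cells 2.24% and 1.98%, and plasmacytoid dendritic-like cells 0.454% and 0.683%. Treg-like cells, the regulatory T lineage, made up 1.97% and 1.26%, 1.57-fold lower (2.37-fold with the 5% limit, 3.19-fold with separate clustering and 5.47-fold with all genes variable). Megakaryocyte or platelet-like cells (0.208% and 0.154%) and basophil or mast cell-like cells (0.113% and 0.0441%) rested on 22 cells or fewer per library. Clusters without a name held 2.09% and 2.80%. Of the 127 unnamed infected cells, 81 formed 1 cluster (T6.1) split from a parent with UMIs of Cd4 and of Cd8b1. T6.1 held 1.78% of infected cells and 1 saline cell, and its leading genes were Gzmb, Gzma and Tnfrsf4. It belongs to no compared class, so the shares and gene values of CD4 and CD8 T-like cells leave it out. All shares are of cells that survived red cell lysis and a sort for propidium iodide-negative live cells, at a median depth that was higher in the infected library. Over the settings, 12 of 95 share ratios changed sign. The order of the 2 erythroid-like shares turned with a minimum of 1000 UMIs per cell, a 5% mitochondrial limit or separate clustering of the libraries. That of the macrophage-like shares turned with called doublets kept, where the infected share was 44.9-fold below the saline share. The order of the neutrophil-like shares turned with the 5% limit, and those of the cDC1-like and cDC2-like shares with separate clustering. The CD4 T-like shares, nearly equal, turned with called doublets kept, the 5% limit, all genes variable, separate clustering (log2 ratio 0.27) or erythroid-like cells left out.

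**Figure D1:**
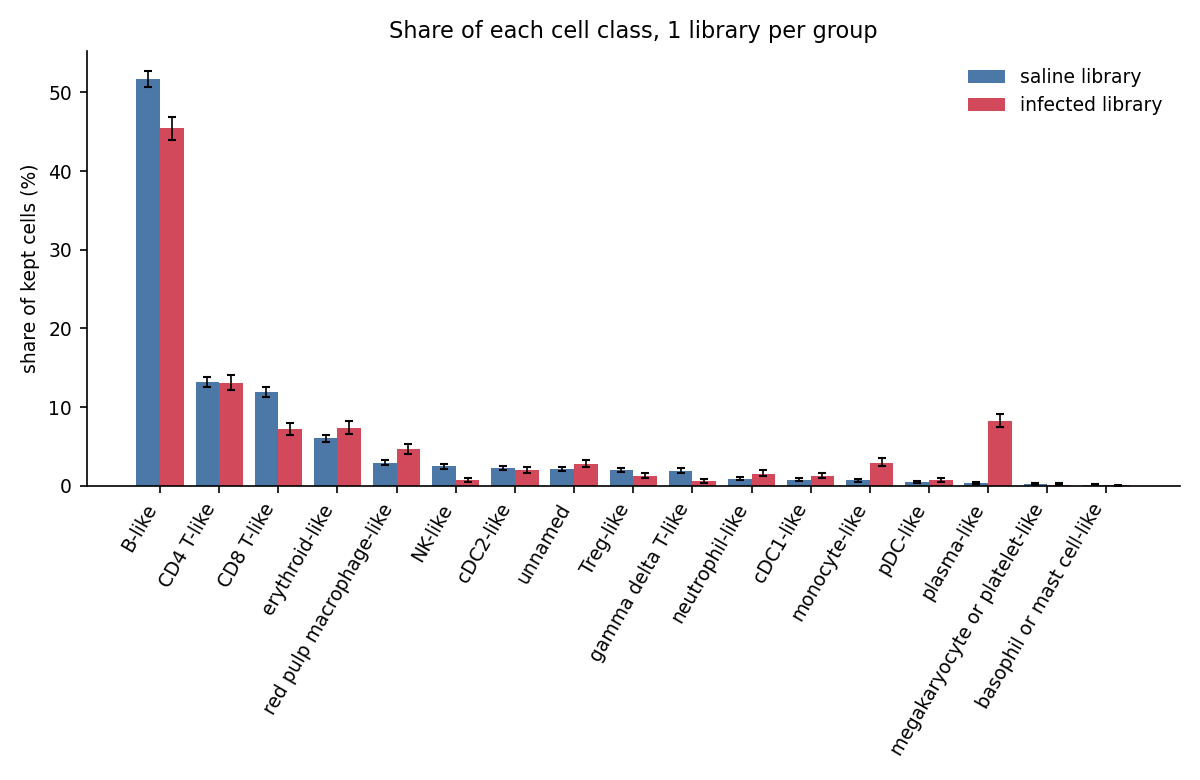
Share of kept cells (%) in each cell class for the saline and infected libraries; bars are shares and error bars exact 95% binomial intervals. Plasma-like cells stood at 0.369% and 8.24%, and NK-like cells at 2.49% and 0.705%.

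The further comparisons asked which genes differed within each class that had at least 100 cells in both libraries, using UMIs summed over its cells. The median log2 ratio of infected over saline over all measured genes was -0.22 in B-like, 0.01 in CD4 T-like, -0.10 in CD8 T-like, -0.23 in red pulp macrophage-like and 1.498 in erythroid-like cells. edgeR's TMM factors shifted every ratio of a class by 0.20 in B-like, 0.26 in macrophage-like and -1.16 in erythroid-like cells. A CPM total without haemoglobin, immunoglobulin, mitochondrial and ribosomal genes shifted them by -0.24 in CD4 T-like, -0.12 in CD8 T-like, -0.14 in macrophage-like and -1.13 in erythroid-like cells. Each gene list is given as the median log2 ratio of its measured members with its percentile among 10000 random lists of the same class and size matched on expression, which such shifts leave in place.

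Infected B-like cells carried more RNA of Socs3, Socs1 and interferon-gamma response genes and less of genes typical of resting and marginal zone B cells. Values in square brackets leave out cluster C18, the deepest B-like cluster, with 42 saline and 173 infected cells. Socs3, a feedback inhibitor of cytokine signalling, stood at 3.23 CPM in saline and 308 CPM in infected cells, a log2 ratio of 6.58 [6.88] (6.21 to 6.96), and its relative Socs1 had a ratio of 3.62 [3.79]. Iigp1, a GTPase that acts on vacuoles of intracellular pathogens, stood at 0.689 and 87.9 CPM, a ratio of 7.00 [7.26] (6.22 to 7.91). Fcer2a, the low-affinity IgE receptor of follicular B cells, stood at 386 and 75.3 CPM (-2.36 [-2.08]), and Cr2, a complement receptor, at 483 and 108 CPM (-2.15 [-1.89]). Of 11120 measured genes, 684 [293] were at least 2-fold higher and 1096 [891] at least 2-fold lower in the infected library (878 and 709 with TMM factors).

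The resting and marginal zone B cell list had a median of -0.85 [-0.66] (percentile 0), with none of its 16 measured members at least 2-fold higher and 7 [6] at least 2-fold lower. Among these were S1pr3, a sphingosine-1-phosphate receptor, at -2.47 [-2.66] (-2.90 to -2.05), and Klf2, a transcription factor of quiescent lymphocytes, at -1.09 [-0.78]. Other genes with the lowest ratios were Trim7 (-2.31 [-1.96]), Cd55, a complement regulator (-2.18 [-1.81]), Grap2 (-2.03 [-1.74]), Id3, an inhibitor of E-protein transcription factors (-1.98 [-1.84]), Adgre5 (-1.97 [-1.87]) and Rgs2 (-1.87 [-1.69]). In the B cell activation and germinal centre list (median 0.71 [0.55], percentile 100), 9 of 20 [6 of 18] members were at least 2-fold higher and 3 [3] lower. The chemokine receptor Cxcr3 was higher at 4.95 [3.55] and Cd83, an activation marker, at 1.76 [1.98], whereas Egr3, an immediate early factor, was lower at -1.66 [-1.39] and Irf4, a factor of plasma cell formation, at -1.20 [-1.14]. After thinning each cell to 1000 UMIs, Cd83 had a UMI in 8.26% of saline and 29.6% of infected B-like cells (22.5% and 71.8% unthinned), against 0.144% and 0.676% of CD4 T-like cells.

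Thinning left out 58 saline and 5 infected B-like cells, whose class medians were 2737 and 5197 UMIs. Fcer2a had a UMI in 30.9% and 8.70% of thinned B-like cells (58.7% and 31.2% unthinned), and in 0.647% of saline CD4 T-like cells, where the median was 3075 UMIs. It was seen in 0 of 592 thinned infected CD4 T-like cells (median 5104 UMIs), which allows up to 0.507%. Cr2 had a UMI in 29.7% and 8.36% (54.3% and 35.0% unthinned).

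All 25 [4 of 23] measured proliferation genes were at least 2-fold higher in infected B-like cells, with a median of 2.30 [0.48] (percentile 100). Birc5, which acts in chromosome segregation, had a ratio of 3.42 [1.37], Plk1, a mitotic kinase, 3.43, Ube2c, of the anaphase-promoting complex pathway, 3.30 [2.16], Pclaf, a partner of PCNA, 3.31 [0.49], and Mki67 2.09 [-0.078]. Part of each ratio came from C18, without which Plk1 had too few UMIs to be measured, Mki67 was not higher and Birc5 and Ube2c still were. The plasma cell and secretory list had a median of 0.61 [0.61] (percentile 100), with 7 of 19 [2 of 19] members at least 2-fold higher and 2 [2] lower. Its chaperone genes Sdf2l1 (2.10 [1.703]) and Calr (0.96 [0.79]) were higher, while Sdc1, a plasma cell surface protein, was lower at -2.59 [-2.42] (-3.39 to -1.88).

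The interferon-gamma GTPase and chemokine list had a median of 1.21 [1.208] in B-like cells (percentile 100), with 14 of 24 [15 of 23] members at least 2-fold higher and none lower. The interferon-stimulated list had a median of 0.35 [0.57] (percentile 100). Of its 27 measured members, 7 [7] were at least 2-fold higher, including Zbp1, a sensor of nucleic acids (2.17 [2.31]), and Ly6a (1.62 [1.77]), and 1 [0], the antiviral gene Ifit3, was at least 2-fold lower (-1.18 [-0.78]). MHC class I genes had a median of 0.49 [0.63] (percentile 99.9; 1 of 16 [3 of 16] at least 2-fold higher), with H2-Q7 at 1.18 [1.397] and H2-K1 at 0.62 [0.79]. MHC class II genes had a median of -0.26 [-0.041], at percentile 5.95 [50.1]. None of 14 was at least 2-fold apart, and their transactivator Ciita had a ratio of -0.67 [-0.398]. Glycolysis genes had a median of 1.22 [0.66] (percentile 100), with 10 of 15 [3 of 14] at least 2-fold higher. Among them, Ldha, lactate dehydrogenase, stood at 1.86 [1.31] and Gapdh at 1.70 [1.001]. Oxidative phosphorylation genes had a median of 0.37 [0.023], at percentile 99.7 [82.8]. Of these, 1 of 20 [0 of 20] was at least 2-fold higher, and cytochrome c (Cycs) stood at 1.19 [0.73]. Serpina3g (2.74 [2.901]), Gadd45g (2.72 [3.04]) and the heat shock gene Hsph1 (2.62 [2.45]) were also among the highest. The dissociation stress and immediate early list had a median of -0.46 [-0.17], at percentile 0.97 [31.8]. Of its members, 3 of 16 [4 of 16] were at least 2-fold higher and 3 [2] lower, with the heat shock gene Hspa1a at 6.16 [6.401] and Egr1 at -1.54 [-1.45]. Haemoglobin RNA, a marker of free RNA in this class, had a median of -3.00 [-2.698]. Most saline B-like cells lay in clusters C0, C4 and C6 and most infected ones in C1, C6 and C18.

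Infected CD4 T-like cells carried more RNA of follicular helper and co-inhibitory genes, and more of T helper 1 effector genes, much of it in clusters T6.0 and T6.3, whose naming is uncertain. Values in square brackets leave these 2 clusters out. Ifng, the interferon-gamma gene, stood at 2.27 and 622 CPM, a log2 ratio of 8.10 [2.88] (7.21 to 9.16). Gzmb, a cytotoxic protease, had 0 UMIs in saline and 1889 CPM in infected cells, at least 2768-fold higher against 3 counts (exact log2 limit 11.14), and Il10, a regulatory cytokine, 0 UMIs and 211 CPM, at least 309-fold higher (7.97). Il21, a helper cytokine for B cells, stood at 0.682 and 109 CPM (7.32 [6.201], 5.77 to 9.61), and the inhibitory receptor Pdcd1 at 4.55 and 236 CPM (5.70 [4.73]). Of 9209 measured genes, 973 [639] were at least 2-fold higher and 693 [535] lower (734 and 1119 with the CPM total that leaves out haemoglobin, immunoglobulin, mitochondrial and ribosomal genes).

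Saline CD4 T-like cells lay mostly in cluster T0 and infected ones in T3 (268 cells), T9 (191), T6.0 (84) and T6.3 (33). T6.0 and T6.3 had no saline cells, and their 10 leading genes held 2 Treg-like markers, Ctla4 and Tnfrsf4, against 1 CD4 T-like marker. Without these 2 clusters, the genes with 0 saline UMIs were higher, against 3 counts, on the log2 scale by at least 5.27 (Gzmb), 4.62 (Il10), 4.16 (Ifi204) and 6.18 (Hspa1a), and Ccl4, Ccl3 and Foxp3 had too few UMIs to be measured.

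The Th1 list had a median of 4.86 [1.61] (percentile 100), with 17 of 21 [12 of 19] members at least 2-fold higher and none [1] lower. The chemokines Ccl4 (12.82, 10.34 to 18.12, on 1 saline UMI) and Ccl3 (10.61, 8.76 to 13.66, on 2) and the receptor Cxcr6 (5.76 [0.12]) were higher with these clusters, as was Tbx21, the Th1-defining transcription factor, at 0.910 and 26.5 CPM (4.86 [3.55], 3.46 to 6.77). Il18r1, a cytokine receptor chain, had a ratio of 0.66 [-0.35] (0.34 to 0.97). The Tfh list had a median of 1.61 [1.94] (percentile 100), with 9 of 14 [9 of 14] members at least 2-fold higher and 2 [2] lower. Cxcr5, which guides cells to B cell follicles, stood at 3.41 and 68.4 CPM (4.33 [4.72], 3.58 to 5.18), and Bcl6, the Tfh-defining repressor, at 5.69 and 25.7 CPM (2.18 [2.67]). In the same list Id3 (-2.58 [-2.17]) and Cd40lg (-1.35 [-1.96]) were lower.

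Of the 14 [11] co-inhibitory and regulatory genes, 13 [11] were at least 2-fold higher and none lower, with a median of 5.28 [3.59] (percentile 100). Lag3, an inhibitory receptor, had a ratio of 10.40 [8.82] (7.92 to 15.70) on 1 saline UMI and Tnfrsf4, a costimulatory receptor, 6.51 [5.16]. Foxp3, the Treg-defining factor, stood at 2.96 and 5.401 CPM (0.87, -0.20 to 1.99), and turned to -0.78 with Treg-like cells counted as CD4 T-like. The naive and resting T cell list had a median of -1.16 [-0.67] (percentile 0), with none of 13 members at least 2-fold higher and 7 [5] lower, including the transcription factors Klf2 (-1.67 [-1.395]) and Lef1 (-1.79 [-1.299]) and Dapl1 (-1.83 [-1.303]), while Satb1 had a ratio of -0.05 [0.16]. The lowest ratios belonged to Ramp1 (-2.40 [-1.86]), Klf3 (-2.29 [-2.24]), the interleukin 6 receptor chain Il6ra (-2.03 [-1.52]), Fam78a (-1.94 [-1.89]), the cold-inducible gene Cirbp (-1.94 [-1.62]) and Rasgrp2 (-1.83 [-1.97]).

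After thinning to 1000 UMIs, Ifng had a UMI in 0.287% of saline and 9.80% (7.52 to 12.5) of infected CD4 T-like cells (0.573% and 21.04% unthinned), against 0.0924% and 0.194% of B-like cells. Cxcr6 was seen in 0.359% and 9.97% (1.22% and 18.7% unthinned) and Pdcd1 in 0.359% and 12.7% (1.15% and 35.0% unthinned). Il10 was seen in 0 of 1392 thinned saline cells, which allows up to 0.216%, and in 6.08% of infected cells (17.2% unthinned). Il21 was likewise seen in 0 of 1392 and in 5.74% (0.215% and 21.04% unthinned). In B-like cells the thinned shares of Cxcr6, Pdcd1, Il10 and Il21 were at most 0.146%. Thinning left out 4 saline and 2 infected CD4 T-like cells. Over the thinned infected cells outside T6.0 and T6.3, the shares were 1.05% (0.341 to 2.43) for Ifng, 0.839% for Cxcr6 and for Il10, 7.34% (5.16 to 10.06) for Pdcd1 and 3.35% (1.93 to 5.39) for Il21; these clusters held no saline cells.

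**Figure D2:**
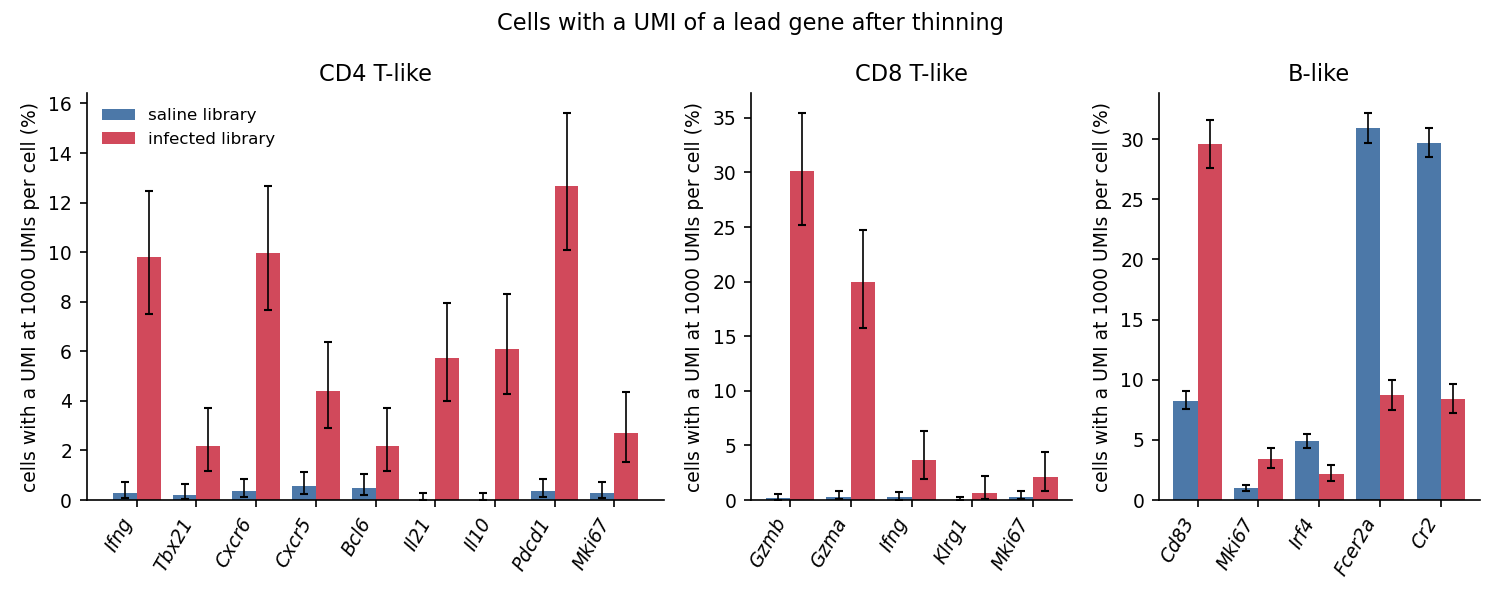
Cells with at least 1 UMI of a lead gene (%) after thinning each cell to 1000 UMIs, in 3 classes of the saline and infected libraries; error bars are exact 95% binomial intervals. Ifng in CD4 T-like cells stood at 0.287% and 9.80% (1.05% without T6.0 and T6.3), and Gzmb in CD8 T-like cells at 0.160% and 30.2%.

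Of 28 measured interferon-stimulated genes, 25 [26] were at least 2-fold higher in infected CD4 T-like cells and none lower, with a median of 1.90 [1.99] (percentile 100). Ly6a had a ratio of 3.84 [3.504] and Ifit2 -0.48 [-0.14]. The unnamed T sub-clusters T13.0, T13.1 and T13.2 held 25, 22 and 15 saline and 0 infected cells and were led by Ifit3 and Ifit1. They belong to no compared class, so the saline levels of this list in CD4 and CD8 T-like cells leave them out. The interferon-gamma list had a median of 1.76 [2.04] (percentile 100), with 19 of 22 [18 of 22] members at least 2-fold higher, among them Gbp3, a guanylate-binding GTPase (3.505 [2.755]), and the transcription factor Irf8 (4.97 [4.69]). Ifi204, a DNA sensor, had 0 UMIs in saline and 36.5 CPM in infected cells, at least 53.5-fold higher against 3 counts (exact log2 limit 5.425). MHC class I genes had a median of 0.62 [0.56] (percentile 98.4; 2 of 16 [0 of 16] at least 2-fold higher), with the proteasome activator Psme2 at 1.27 [0.85] and H2-K1 at 0.46 [0.46]. Proliferation genes had a median of 2.00 [0.76] (percentile 100), with 11 of 16 [5 of 12] at least 2-fold higher; Mki67 had a ratio of 3.26 [2.655], Hmgb2 1.21 [0.84] and Pcna 0.38 [0.066]. Glycolysis genes had a median of 1.79 [1.44] (percentile 100; 12 of 15 [11 of 14] at least 2-fold higher), with the lactate transporter Slc16a3 at 5.71 [4.67] and Gapdh at 2.22 [1.805], and oxidative phosphorylation genes 0.65 [0.38] (percentile 99.3; 2 of 20 [0 of 20] at least 2-fold higher), with Cycs at 1.34 [0.85]. The dissociation stress list had a median of 0.37 [0.55], at percentile 88.2 [99.9]. Of its members, 5 of 16 [4 of 15] were at least 2-fold higher, with Hspa1a at 0 UMIs and 38.1 CPM. Haemoglobin RNA had a median of -2.15 [-1.83] and immunoglobulin RNA 1.42 [0.012], with Igkc at 3.72 [2.29]; the immunoglobulin median turned to -0.064 with called doublets kept.

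Infected CD8 T-like cells carried high levels of granzyme RNA. Gzmb stood at 2.21 and 3623 CPM, a log2 ratio of 10.68 (9.84 to 11.68), Gzma at 15.5 and 2241 CPM (7.18, 6.85 to 7.52) and Gzmk at 1.01 and 103 CPM (6.68), all proteases of cytotoxic granules. Ifitm1, an interferon-induced membrane protein, had a ratio of 10.64 (8.78 to 13.68) on 2 saline UMIs, and Ifng stood at 2.21 and 44.1 CPM (4.32, 3.42 to 5.37). Of 8826 measured genes, 430 were at least 2-fold higher and 650 lower (356 and 860 with the reduced CPM total). The order of these counts turned with a minimum of 1000 UMIs per cell (814 and 693), resolution 2 (676 and 644), all genes variable (673 and 648) and separate clustering (703 and 647). They were 272 and 481 with the 5% mitochondrial limit. Saline cells lay mostly in clusters T1 and T4 and infected cells in T7 (216 cells) and T12 (87). Gzmb, Gzma and Gzmk were among the 10 leading genes of T12, which held no saline cells, and not among those of T7. Values without T12 were not computed. The unnamed infected cluster T6.1, also led by Gzmb and Gzma, is not part of this class.

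The cytotoxic effector list had a median of 2.18 (percentile 100), with 13 of 17 members at least 2-fold higher and none lower. Ccl5, a chemokine of effector T cells, stood at 1352 and 7299 CPM (2.43) and Ccl4 had a ratio of 4.97, whereas the transcription factor Eomes stood at 52.1 and 36.0 CPM (-0.53). Klrg1, a marker of terminal effectors, had too few UMIs to be measured and was seen in 0 of 1249 thinned saline cells, which allows up to 0.240%, and in 0.615% of infected cells. Of 9 measured co-inhibitory genes, 7 were at least 2-fold higher (median 3.09, percentile 100), with Pdcd1 at 6.34, Lag3 at 4.90 and Ikzf2 at -0.18 (-0.45 to 0.08). Naive and resting genes had a median of -0.50 (percentile 0), with 3 of 13 at least 2-fold lower and none higher; the egress receptor S1pr1 (-1.26) and Klf2 (-1.11) were among the 3, and Satb1 had a ratio of 0.42. The lowest ratios were those of Id3 (-2.91), Rgcc (-2.81), Tent5a (-2.15), Adgre5 (-1.84), Cirbp (-1.77), Arl5c (-1.67), Rasgrp2 (-1.66) and Klf3 (-1.57). Lgals3, a galectin, was higher at 5.87, Gadd45g at 5.56 and Ly6a at 5.55.

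After thinning, Gzmb had a UMI in 0.160% of saline and 30.2% (25.2 to 35.5) of infected CD8 T-like cells (0.556% and 42.8% unthinned), against 0.0185% and 0.292% of B-like cells, at class medians of 3757 and 6262 UMIs. Gzma was seen in 4 of 1249 (0.320%) and 65 of 325 thinned cells (1.51% and 28.9% unthinned), against 0.203% and 0.292% of B-like cells. Thinning left out 9 saline and 0 infected CD8 T-like cells.

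In CD8 T-like cells 21 of 25 interferon-stimulated genes were at least 2-fold higher and none lower (median 1.67, percentile 100), as were 19 of 22 in the interferon-gamma list (median 1.77, percentile 100). The antiviral synthetase Oas1a had a ratio of 3.14, Iigp1 4.09 and the chemokine Cxcl10 5.13. MHC class I genes had a median of 0.59 (percentile 99.97; none of 16 at least 2-fold apart), with H2-T22 at 0.96 and H2-K1 at 0.61. Proliferation genes had a median of 1.55 (percentile 100), with 11 of 17 at least 2-fold higher; Ube2c had a ratio of 4.69, Mki67 2.74 and Pcna -0.05 (-0.35 to 0.24), which turned to 1.33 with a minimum of 1000 UMIs per cell. Glycolysis genes had a median of 0.58 (percentile 99.9; 4 of 13 at least 2-fold higher), with Hif1a, the hypoxia-inducible factor, at 1.57 and Gapdh at 1.25, and oxidative phosphorylation genes 0.31 (percentile 98.0; none of 20 at least 2-fold apart), with Cox5a at 0.68. The dissociation stress list had a median of 0.27 (percentile 96.8; 4 of 15 at least 2-fold higher), with Hspa1b at 7.84 on 1 saline UMI. Haemoglobin RNA had a median of -3.29 and immunoglobulin RNA -0.83, with Ighm at -1.25; the immunoglobulin median turned to 0.62 with separate clustering of the libraries.

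**Figure D3:**
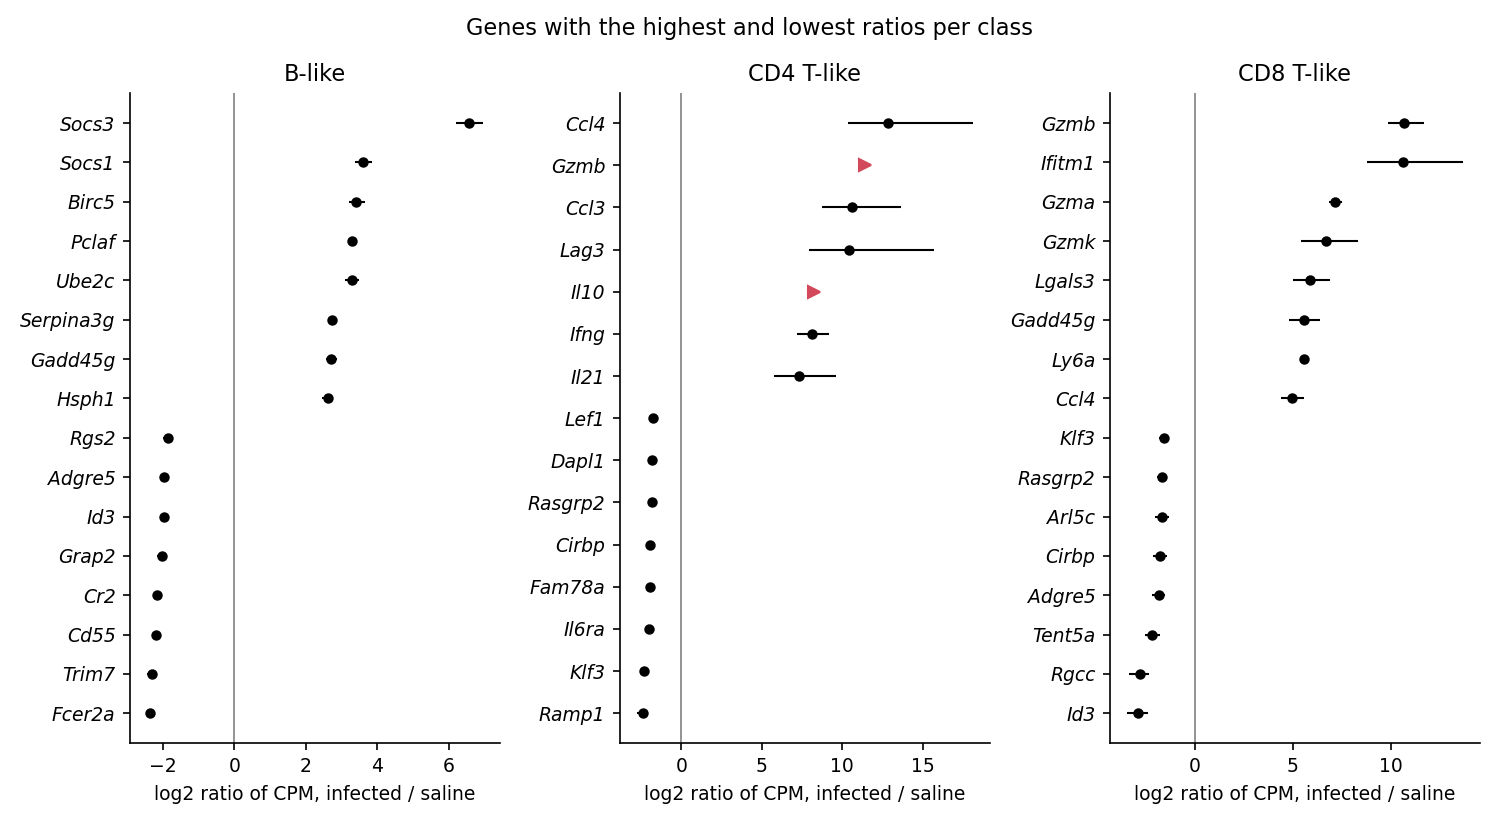
Log2 ratio of CPM, infected over saline, of genes among the 8 highest and 8 lowest ratios in B-like, CD4 T-like and CD8 T-like cells; bars on the points are exact 95% counting intervals, and a red triangle marks a lower bound where saline had 0 UMIs. Gzmb in CD8 T-like cells lies at 10.68 and Fcer2a in B-like cells at -2.36.

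Infected erythroid-like cells carried more RNA of interferon-gamma and MHC class I genes. Values in square brackets leave out cluster C13, the deepest erythroid-like cluster, which held 242 of the 335 infected and 31 saline cells. Iigp1 stood at 1.33 and 736 CPM, a log2 ratio of 9.11 [7.98] (7.99 to 10.56), and Gbp2, a guanylate-binding GTPase, at 2.66 and 451 CPM (7.40 [5.899], 6.60 to 8.36). B2m, the light chain of MHC class I, stood at 280 and 1937 CPM (2.79 [2.82]). Alas2, which starts haem synthesis in red cell precursors, stood at 1667 and 141 CPM (-3.57 [-0.29], -3.65 to -3.48), and Bpgm, which makes a regulator of oxygen release, at 1737 and 118 CPM (-3.88 [-0.44]). Haemoglobin genes took 61.4% of the UMIs of saline and 4.85% of those of infected erythroid-like cells, and the median over all genes was 1.498 [0.553]. Of 9289 genes, 6108 [1038] were at least 2-fold higher and 718 [239] lower, against 2415 and 1547 with TMM factors and 2476 and 1532 with the reduced CPM total.

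In erythroid-like cells the interferon-gamma list had a median of 4.08 [2.99] (percentile 100), with 21 of 23 [11 of 14] members at least 2-fold higher and none [1] lower; Igtp, another GTPase, had a ratio of 5.38 [4.34]. MHC class I genes had a median of 2.82 [2.69] (percentile 100), with 16 of 16 [10 of 13] at least 2-fold higher and H2-Q7 at 3.48 [3.25]. Interferon-stimulated genes had a median of 2.17 [2.485] (percentile 98.5), with 18 of 26 [18 of 22] at least 2-fold higher and 2 [0] lower; Zbp1 had a ratio of 6.24 [5.37], the antiviral gene Rsad2 -3.12 [0.37] and the ubiquitin-like Isg15 0.45 [2.42], which turned to -0.71 with TMM factors. The erythroid maturation list had a median of -0.67 [0.54] (percentile 0 [53.8]). Without C13 it lay at the level of the typical gene. It stood at 0.040 with separate clustering of the libraries, where the median over all genes was 1.88. Of its 20 members, 7 [0] were at least 2-fold lower and 3 [4] higher, among the latter the early genes Klf1 (1.66 [1.53]), an erythroid transcription factor, and Car1 (2.09 [1.62]), a carbonic anhydrase. Other genes lower with C13 were Tent5c (-3.78 [-0.46]), the ubiquitin ligase Ube2o (-3.62 [-0.71]), Cd36 (-3.53 [-0.042]), Xpo7 (-3.34 [0.215]) and Ypel3 (-3.27 [-0.16]). Other high genes were Tubb3 (8.07, 6.21 to 11.12, on 2 saline UMIs), Lgals9 (5.14 [1.96]), Lap3 (5.01) and Cited4 (4.84). Tubb3, Lap3 and Cited4 had too few UMIs to be measured without C13.

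Proliferation genes had a median of 1.20 [0.84] in erythroid-like cells, which lay at percentile 1.98 [98.6] and moved to 0.04 with TMM factors; the replication gene Mcm3 had a ratio of 2.30 [1.25], and 16 of 25 [7 of 25] members were at least 2-fold higher. Glycolysis genes had a median of 2.37 [1.32] (percentile 98.4; 11 of 13 [6 of 10] at least 2-fold higher; Gapdh 3.07 [1.799]), oxidative phosphorylation genes 2.28 [0.99] (percentile 96.8; 20 of 20 [10 of 20] at least 2-fold higher; Cycs 3.12 [1.46]) and the dissociation stress list -0.49 [0.43] (percentile 0 [17.4]; 3 of 16 [3 of 14] higher and 5 [4] lower; Hspa1a 8.29 [8.78] on 1 saline UMI). Immunoglobulin RNA had a median of -2.43 [-1.93], with Iglc2 at -4.10 [-2.84]. Saline cells lay mostly in C12, C15 and C20 and infected cells in C13.

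Infected red pulp macrophage-like cells carried more RNA of inflammatory genes and less of the fixed list of iron, haem and phagocytosis genes. Ccl2, which attracts monocytes, stood at 2.91 and 388 CPM (log2 ratio 7.06, 5.19 to 10.12, on 2 saline UMIs), and Cxcl10, an interferon-induced chemokine, at 16.0 and 1555 CPM (6.60, 5.75 to 7.61). Hmox1, which breaks down haem, stood at 2293 and 4733 CPM (1.04, 0.95 to 1.14), and Spic, the transcription factor that defines these macrophages, at 649 and 909 CPM (0.49, 0.29 to 0.68). Slc40a1, the iron exporter ferroportin, stood at 1959 and 195 CPM (-3.33, -3.65 to -3.02), and Vcam1, an adhesion molecule, at 2443 and 678 CPM (-1.85). Saline cells lay in cluster C11 (287 of 309) and infected cells in C16 (210 of 211), at medians of 1525 and 1306 UMIs. With called doublets kept, the infected share of this class was 44.9-fold below the saline share. The naming of the infected cells thus depends on the doublet filter. Of 5088 genes, 747 were at least 2-fold higher and 1512 lower (1100 and 1245 with TMM factors). These counts include B cell RNA, whose markers stood at a median of 41.2% of their B-like level in the saline and 4.62% in the infected class, and Malat1, Neat1 and Xist, which mark nuclear RNA, had a median ratio of -2.66. B cell RNA in the saline CPM total would also raise the ratios of the macrophages' own genes, such as Hmox1 and Spic, to an unmeasured extent. Mitochondrial UMIs made up 6.37% of the saline and 2.06% of the infected class.

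The inflammatory myeloid list had a median of 3.28 in this class (percentile 100), with 11 of 15 members at least 2-fold higher and none lower; Ms4a4c had a ratio of -0.61 (-1.26 to 0.01). The chemokine genes Ccl12 and Ccl8 had 0 saline UMIs and stood at 390 and 313 CPM in infected cells, at least 89.5-fold and 71.8-fold higher against 3 counts (exact log2 limits 6.17 and 5.85). Acta2 (6.39, 3.86 to 11.72, on 1 saline UMI), Procr (6.04), Socs3 (5.81) and Lilr4b (5.51) were also among the highest. Of 24 iron, haem and phagocytosis genes, 11 were at least 2-fold lower and 3 higher (median -0.58, percentile 0.17). Cd163, the haemoglobin scavenger receptor, stood at 140 CPM and 0 UMIs, at least 21.7-fold lower (exact log2 limit -4.11), and transferrin (Trf) had a ratio of -3.85, whereas Fth1, the heavy chain of the iron store ferritin, stood at 8701 and 28430 CPM (1.71) and the scavenger receptor Msr1 had a ratio of 4.02. After thinning, Slc40a1 had a UMI in 58.8% of saline and 17.4% of infected cells (69.9% and 27.5% unthinned), Vcam1 in 66.8% and 34.0% (79.3% and 43.6%) and Hmox1 in 64.7% and 86.8% (79.6% and 85.8%). All 3 were at most 0.437% in thinned B-like cells of either library, and 122 saline and 67 infected macrophage-like cells were left out as too shallow.

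The interferon-gamma list had a median of 2.35 in macrophage-like cells (percentile 100), with 19 of 23 members at least 2-fold higher and 1, Ciita (-2.72), lower; Gbp2b had 0 saline UMIs and 131 CPM, at least 29.99-fold higher against 3 counts (exact log2 limit 4.56). Interferon-stimulated genes had a median of 0.78 (percentile 97.6; 8 of 19 at least 2-fold higher and 1 lower), with Zbp1 at 3.79 and Isg15 at 3.06. MHC class II genes had a median of -0.86 (percentile 0.895), with none of 13 at least 2-fold higher and 5 lower; the invariant chain Cd74 had a ratio of -1.25, H2-Ob -2.96 and H2-DMb1 0.80. The B cell RNA of the saline class may bear on these MHC class II values, to an extent that was not measured. MHC class I genes had a median of 0.17 (percentile 61.9; 4 of 16 at least 2-fold higher and 2 lower), with Psme2 at 1.60 and the trimming peptidase Erap1 at -1.85. Proliferation genes had a median of 3.27 (percentile 100), with 12 of 15 at least 2-fold higher; Cenpf had a ratio of 4.30 on 3 saline UMIs and Pcna 0.28 (-0.23 to 0.77). Glycolysis genes had a median of 2.12 (percentile 100; 9 of 11 at least 2-fold higher; Pgam1 3.01, Gapdh 2.70) and oxidative phosphorylation genes 1.12 (percentile 99.2; 14 of 20 at least 2-fold higher; Cycs 2.71). The dissociation stress list had a median of -0.92 (percentile 3.02; 2 of 15 at least 2-fold higher and 7 lower), with Atf3 at 3.91 and Fosb at -3.90. The 8 genes with the lowest ratios were Cr2 (-6.79), Mef2c (-6.29), Siglecg (-6.22), Cd1d1 (-5.78), Fcmr (-5.66), Cd55 (-5.42), Klhl24 (-5.41) and Slpi (-5.19), of which Cr2 and Fcmr are B-like markers and Cr2, Cd1d1 and Cd55 are in the resting B cell list. Haemoglobin RNA had a median of -5.14 and immunoglobulin RNA -3.30, with Igkc at -1.72.

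**Figure D4:**
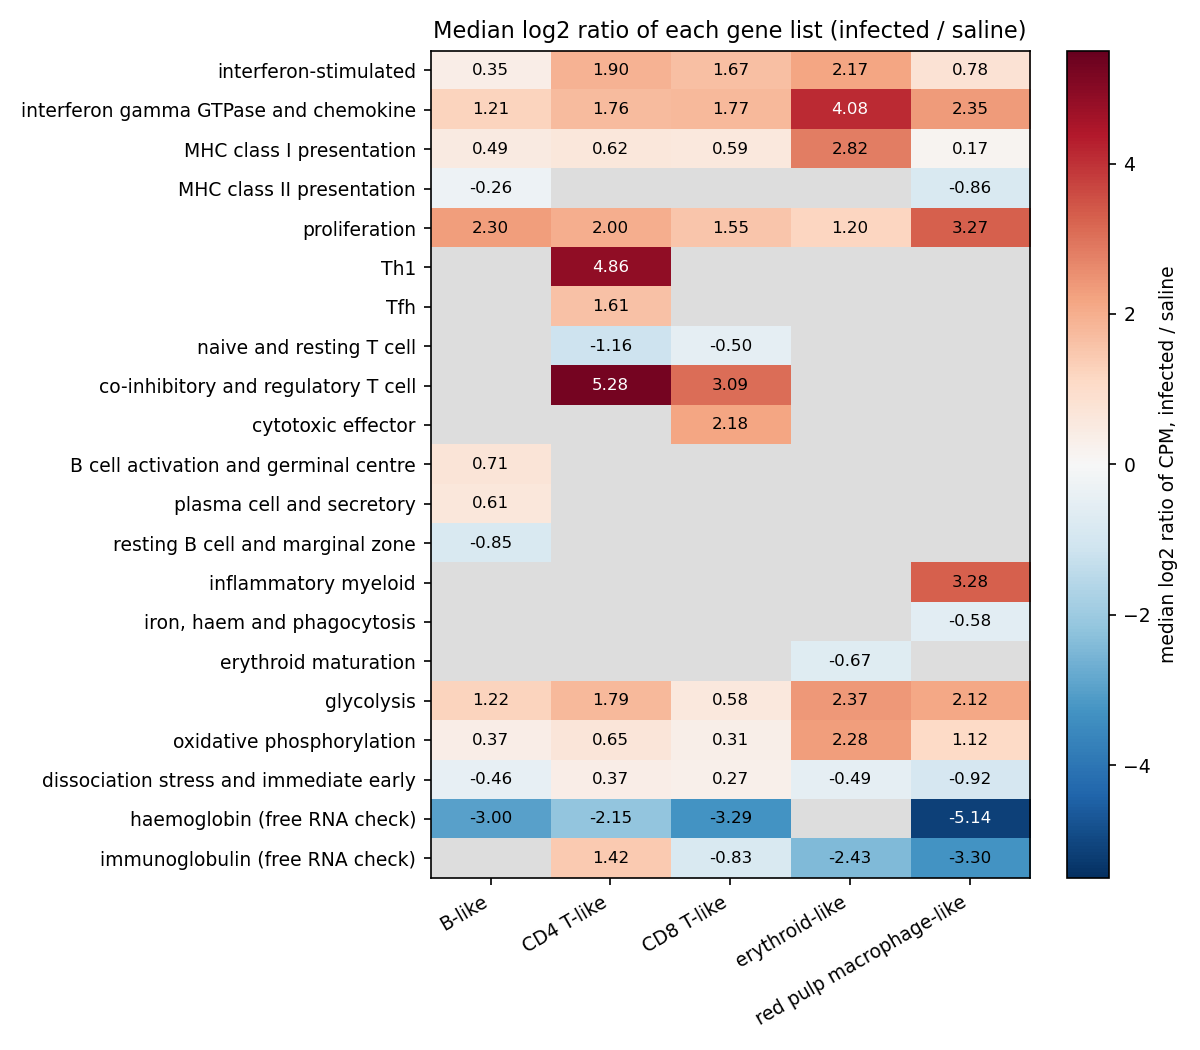
Median log2 ratio, infected over saline, of each gene list (rows) in the 5 classes with at least 100 cells per library (columns), on a colour scale with the value printed in the cell; grey cells were not computed. The interferon-gamma list lies above 1 in every column, from 1.21 in B-like to 4.08 in erythroid-like cells.

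Classes with at least 50 cells in both libraries were added after the data were seen. Infected monocyte-like cells carried high levels of inflammatory RNA: Cxcl9, an interferon-gamma-induced chemokine, stood at 22.6 and 2853 CPM (log2 ratio 6.98, 6.06 to 8.11), Cxcl10 at 100.3 and 1376 CPM (3.78), the acute phase gene Saa3 at 115 and 6112 CPM (5.73) and Hmox1 at 75.2 and 5303 CPM (6.14). Nos2, the inducible nitric oxide synthase, had 0 UMIs and 462 CPM, at least 61.4-fold higher against 3 counts (exact log2 limit 5.64). Cx3cr1, a receptor of patrolling monocytes, stood at 331 and 12.3 CPM (-4.74) and Ccr2, which brings monocytes out of bone marrow, at 717 and 300 CPM (-1.25), while Ly6c2 stood at 792 and 904 CPM (0.19, 0.02 to 0.37). Saline cells lay in cluster C26 (74) and infected cells in C24 (133). C24 was named narrowly, with a score of 2.158 against 1.752 for red pulp macrophage-like cells, and its 10 leading genes held 1 marker of each, that of macrophage-like cells being Hmox1. In all, 977 of 6343 genes were at least 2-fold higher and 1181 lower (1555 and 631 with TMM factors).

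In monocyte-like cells 23 of 24 inflammatory genes were at least 2-fold higher (median 3.87, percentile 100), as were 24 of 26 in the interferon-gamma list (median 3.46), 13 of 16 MHC class I genes (median 1.34) and 18 of 22 iron, haem and phagocytosis genes (median 2.47), with Fth1 at 3.38 and the engulfment receptor Mertk at 4.89 on 1 saline UMI. Ccl4 (10.73) and Iigp1 (8.98) rested on 1 saline UMI each and Il1rn (6.96) on 2. Of 13 MHC class II genes, 7 were at least 2-fold higher and 3 lower (median 1.85, percentile 99.98), with H2-Aa at 790 and 3332 CPM (2.08), Cd74 at 1.85, the costimulatory genes Cd40 at 2.90 and Cd86 at 2.58, and H2-Ob at -2.35. Proliferation genes had a median of -0.61 (percentile 6.80), with Ube2c at -1.67 and Mcm5 at 2.78 (0.19 to 8.12).

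Neutrophil-like cells, all in cluster C22, had interferon-gamma genes at a median of 3.31 (21 of 22 at least 2-fold higher, percentile 100), with Gbp2 at 9.66 and 1472 CPM (7.25, 5.39 to 10.30, on 2 saline UMIs) and Cxcl10 at 0 UMIs and 1670.0 CPM, at least 115-fold higher against 3 counts (exact log2 limit 6.55). Their MHC class I median was 2.17 (H2-Q7 3.52) and their inflammatory median 2.78, while S100a8, a granulocyte alarmin, had a ratio of -0.76, the interleukin Il1b -0.60 and the inhibitory ligand Cd274 2.70. The S100a8 ratio turned to 0.00041 with the 5% mitochondrial limit and to 0.086 with each cell weighted equally. Counts at least 2-fold higher and lower were 969 and 543 of 3574, at class medians of 1507 and 5124 UMIs, against 403 and 372 with the deeper library thinned and 293 and 303 with the 5% mitochondrial limit.

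Dendritic cDC2-like cells (C9) had interferon-gamma genes at a median of 2.36 (17 of 21 at least 2-fold higher and 1 lower, percentile 100) and inflammatory genes at 1.89 (10 of 15 higher), with Cxcl9 at 6.03, Ifitm1 at 5.60, Cd86 at 2.497, Cd40 at 1.89, Il12b at 0.01 (-1.04 to 1.01), Ciita at -1.23, Mef2c at -4.12 and the lectin Cd209d at -4.46; the MHC class II median was -0.08 (percentile 13.1). B-like markers stood at 9.22% of their B-like level in saline and 0.293% in infected cDC2-like cells, and immunoglobulin RNA had a median of -4.58. Their cDC1-like counterparts (C23) had an interferon-gamma median of 1.21 (percentile 99.98) and an inflammatory median of 0.97, which turned to -0.016 with separate clustering, with Cxcl9 at 1.02, Cd40 at 0.92, Socs3 at 6.94 (4.44 to 12.25, on 1 saline UMI), Tnf at -3.08, Apoe at -4.91 and Apol7c at 901 and 1.47 CPM (-9.26, -14.56 to -6.77). Il12b, a chain of interleukin 12, stood at 87.0 CPM in saline and 0 UMIs in infected cDC1-like cells, at least 19.7-fold lower against 3 counts (exact log2 limit -3.93). Their MHC class II median was -0.00 (percentile 34.5). Genes at least 2-fold higher and lower numbered 618 and 935 of 6180 in cDC2-like cells (475 and 1156 with the reduced CPM total, 636 and 620 with the 5% mitochondrial limit) and 532 and 330 of 4328 in cDC1-like cells (387 and 457, 640 and 627 with each cell weighted equally and 568 and 550 with separate clustering).

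Treg-like cells (T5) had interferon-gamma genes at a median of 1.17 (9 of 16 at least 2-fold higher, percentile 100), with Gbp2 at 2.999 and the receptor Ifngr1 at 2.90. Their Th1 median was 0.83 (percentile 99.99) and turned to -0.89 with separate clustering of the libraries, with Gzmb at 3.91 and S100a4 at -2.39, and their co-inhibitory median 0.93 (percentile 99.95), with Ctla4 at 1.75 and Tnfrsf9 at 1.74; Id3 had a ratio of -3.89 (-6.19 to -2.31). In total 171 of 3611 genes were at least 2-fold higher and 277 lower, against 277 and 722 with separate clustering.

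In the GENCODE M21 annotation of build mm10, to which 32158 of the 32286 feature identifiers belong, Ifng (ENSMUSG00000055170) spans chromosome 10 from 118441046 to 118445892 and Gzmb (ENSMUSG00000015437) chromosome 14 from 56258838 to 56262260. Slc40a1 (ENSMUSG00000025993) spans chromosome 1 from 45908068 to 45926523, Fcer2a (ENSMUSG00000005540) chromosome 8 from 3681737 to 3694175, Alas2 (ENSMUSG00000025270) chromosome X from 150547375 to 150570638 and Iigp1 (ENSMUSG00000054072) chromosome 18 from 60376027 to 60392634. The UMI counts are per gene, so no exon is assigned to them.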

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

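Of the tests in this part, the single receptor line of the GFP cells and free RNA as a source of the interferon-gamma list were written down before their values were seen; the others were chosen after the result was seen.

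The first pattern is a signal in data that no comparison used. The added feature named GFP had 517 UMIs in 19 infected cells (2 to 65 each, median 20) and 0 UMIs in saline, which allows up to 0.0284% of saline cells. Of the 19 cells, 8 lay in T9 (of 191 infected cells), 5 in T6.0 (of 84), 3 in T6.1 (of 81), 2 in T6.3 (of 33) and 1 in the cDC2-like cluster C9 (of 90), while 0 of 2063 infected B-like cells had one, which allows up to 0.145%. Free GFP RNA would spread over the classes, but 94.7% (74.0 to 99.9) of the GFP cells lay in CD4 T-like and mixed T clusters, which hold 15.9% of infected cells, so this explanation is excluded. A single transferred T cell receptor line could also carry GFP, but only 2 of the 18 T cells with GFP had a UMI of a Trbv gene, 1 each of 2 different genes (50%, 1.26 to 98.7), so the data cannot tell. Of the 8 with a UMI of a Trav gene, 2 shared the leading gene (25.0%, 3.19 to 65.1). No prediction was written for Trav genes, and with so few cells this count cannot tell either. The labels mention no GFP.

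The second pattern is that the 2 phagocyte classes lay on opposite sides, which flagged 3 lists; the difference between classes was not tested. MHC class II genes had a median log2 ratio of 1.85 in monocyte-like and -0.86 in red pulp macrophage-like cells. Iron, haem and phagocytosis genes had 2.47 and -0.58, and proliferation genes -0.61 and 3.27. Many iron, haem and phagocytosis genes, such as Spic, Hmox1, Slc40a1 and Cd5l, are also markers that name red pulp macrophage-like cells. The values of that list are thus not independent of the naming. Both classes lay in different clusters in the 2 libraries, and the infected monocyte-like cluster C24 scored 2.158 as monocyte-like against 1.752 as red pulp macrophage-like, so the contrast also rests on its name. B cell RNA in the saline macrophage cluster could lower such ratios: B-like markers stood there at a median of 41.2% of their level in saline B-like cells, against 4.62% in the infected class and 0.568% in saline CD4 T-like cells. This fits the explanation for B-like markers such as Cr2, Fcmr and H2-Ob. How much of the other MHC class II RNA it could supply was not measured. B cell RNA in the saline CPM total would also raise the ratios of the macrophages' own genes, such as Hmox1 and Spic. That extent was not measured either. Loss of nuclear RNA in the infected macrophage cluster fits as well, with Malat1, Neat1 and Xist at a median of -2.66, lower than in any other class (next -1.47 in erythroid-like cells). The 2 explanations are not independent. Malat1 stood at 26238 CPM in saline B-like and 20074 CPM in saline macrophage-like cells, so B cell RNA could supply part of it there. A prediction took loss of nuclear RNA as the only change. Hmox1, Spic and Cd5l of the same cells would then be lower to the same extent as Slc40a1 and Vcam1. This assumes that such a loss lowers messenger RNAs as well, which was not measured. Hmox1 (1.04), Spic (0.49) and Cd5l (-1.13) lay above Slc40a1 and Vcam1. The lowest lower bound, that of Cd5l, was -1.413, against upper bounds of -3.02 for Slc40a1 and -1.68 for Vcam1. The comparison genes are markers of the class and may have changed for other reasons, and Cd5l was itself lower. The test therefore cannot decide whether such a loss bears on Slc40a1 and Vcam1 at all.

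The third pattern is the interferon-gamma list, which was higher in infected cells of all 10 classes. Free RNA may carry such transcripts between droplets, but the smallest summed level of the list in a class other than erythroid-like cells was 76.7% of its level over all infected cells (B-like), while haemoglobin, which free RNA sets there, reached at most 21.2% (monocyte-like). A deeper infected library could raise apparent levels, but infected cells shallower than the saline median of their class, set against saline cells at or above it, still had the list higher in the 6 classes with at least 20 such cells, with a lowest lower bound of 1.128 (cDC1-like). Free RNA is thus excluded as the whole source of the list's level in infected classes other than erythroid-like cells. The test did not measure the rise over saline. In B-like cells the list already stood at 1828 CPM in saline, against 3217 CPM in infected cells. How far free RNA adds to the rise therefore stays open. Depth is excluded as the whole cause in these 6 classes. CD8 T-like, Treg-like, monocyte-like and neutrophil-like cells had at most 13 shallower infected cells, so depth stays open there as well. Infection is the study's own contrast and library and treatment cannot be told apart with 1 library per group.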

How the results depend on the processing

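No paired analysis was possible because each group has 1 sample. Over all alternatives, 3120 of 3143 log2 ratios of named genes (248 results), 953 of 970 list medians (76 results) and 83 of 95 share ratios (14 results) kept their sign. For genes this is partly fixed in advance. At least 10 or 100 UMIs per gene, or leaving out genes that free RNA could set, cannot alter a gene's own ratio. These settings gave 248, 222 and 230 of the gene values. Many named genes were also picked for extreme ratios in these same data. The settings that leave out a deepest cluster, the 2 CD4 T-like clusters or genes that free RNA could set, that count Treg-like cells as CD4 T-like, or that admit classes of at least 50 cells were added after the data were seen. Ratios of shares and of genes are log2. The cause was not tested for any value here, except that a higher or lower UMI minimum per gene measures fewer or more genes by construction, a scaling moves all genes of a class alike, and a left-out cluster takes its cells with it.

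Over the settings the log2 ratio of Fcer2a, B-like lay between -2.40 and -2.08. In the settings where they could be computed, the log2 ratio of Slc40a1, red pulp macrophage-like lay between -3.47 and -3.06 and the log2 share ratio, monocyte-like between 2.08 and 2.11, a value that rests on the narrow name of cluster C24. Other values kept their sign but ranged by 1.5-fold or more: the log2 ratio of Gzmb, CD8 T-like from 10.12 to 11.58, the log2 ratio of Socs3, B-like from 6.00 to 6.97 and the log2 share ratio, NK-like from -3.165 to -1.77.

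At most 5% mitochondrial UMIs per cell altered most shares. The log2 share ratio, B-like went from -0.19 to -0.46, CD4 T-like from -0.01 to 0.15, CD8 T-like from -0.73 to -0.25, the log2 share ratio, NK-like from -1.82 to -3.165, Treg-like from -0.65 to -1.25, gamma delta T-like from -1.65 to -0.51, cDC1-like from 0.70 to 0.22, plasma-like from 4.48 to 3.65 and red pulp macrophage-like from 0.67 to 1.53. The log2 share ratio, erythroid-like turned from 0.29 to -2.15 and the log2 share ratio, neutrophil-like from 0.82 to -0.28. The immunoglobulin median turned from 1.42 to -1.45 in CD4 T-like cells, with Igkc from 3.72 to -1.19, and from -0.83 to 1.87 in CD8 T-like cells; S100a8 in neutrophil-like cells turned from -0.76 to 0.00041. Genes at least 2-fold higher in infected, CD8 T-like numbered 272 instead of 430. Monocyte-like and plasmacytoid dendritic-like shares, and gene values of erythroid-like, monocyte-like, red pulp macrophage-like and Treg-like cells, could not be computed there.

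With called doublets kept, the log2 share ratio, red pulp macrophage-like turned to -5.49 and the immunoglobulin median in CD4 T-like cells to -0.064; gene values of red pulp macrophage-like cells could not be computed. With a minimum of 1000 UMIs per cell, the log2 share ratio, CD8 T-like was -0.54 and the log2 share ratio, erythroid-like turned to -1.57, genes at least 2-fold higher in infected, CD8 T-like numbered 814, and erythroid-like gene values could not be computed.

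At Leiden resolution 2 the log2 share ratio, CD8 T-like was -0.54 and the log2 share ratio, cDC2-like went from -0.18 to -0.54; genes at least 2-fold higher in infected, CD8 T-like numbered 676 and the immunoglobulin median there turned to 0.24. With all genes eligible as variable genes, the log2 share ratio, CD8 T-like was -0.53, Treg-like -2.45 and gamma delta T-like -0.94; genes at least 2-fold higher in infected, CD8 T-like numbered 673, their immunoglobulin median turned to 0.33, and Treg-like gene values could not be computed.

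With each library clustered on its own, the log2 share ratio, CD4 T-like turned to 0.27, and was for CD8 T-like -0.56, Treg-like -1.67, plasma-like 2.67 and cDC2-like 0.24 (from -0.18), while the log2 share ratio, cDC1-like turned to -0.044 and the log2 share ratio, erythroid-like to -0.53. Genes at least 2-fold higher in infected, CD8 T-like numbered 703, with an immunoglobulin median of 0.62. The erythroid maturation median turned from -0.67 to 0.040, the Th1 median in Treg-like cells from 0.83 to -0.89 and the inflammatory myeloid median in cDC1-like cells from 0.97 to -0.016.

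With edgeR TMM factors, genes at least 2-fold lower in infected, B-like numbered 709 instead of 1096, and in erythroid-like cells 2415 were higher instead of 6108 and 1547 lower instead of 718; Isg15 in erythroid-like cells turned from 0.45 to -0.71 and the MHC class II median in cDC2-like cells from -0.08 to 0.051. With the CPM total without haemoglobin, immunoglobulin, mitochondrial and ribosomal genes, genes at least 2-fold lower in infected, CD4 T-like numbered 1119 instead of 693, and in erythroid-like cells 2476 were higher and 1532 lower, with Isg15 at -0.68. With each cell weighted equally, S100a8 in neutrophil-like cells turned to 0.086.

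With at least 10 UMIs per gene, genes at least 2-fold lower in infected numbered 1093 in CD4 T-like, 1048 instead of 650 in CD8 T-like, 1113 in erythroid-like and 2911 instead of 1512 in red pulp macrophage-like cells, where 1140 were higher instead of 747. With at least 100 UMIs per gene, genes at least 2-fold lower in infected numbered 704 in B-like, 330 in CD4 T-like, 261 in CD8 T-like, 393 in erythroid-like and 403 in red pulp macrophage-like cells, and genes at least 2-fold higher in infected 255 in CD8 T-like and 388 in red pulp macrophage-like cells; the dissociation stress median in CD8 T-like cells turned from 0.27 to -0.024.

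Without its deepest cluster, genes at least 2-fold higher in infected, B-like numbered 293 instead of 684 and Mki67 turned from 2.09 to -0.078. Without T6.0 and T6.3, genes at least 2-fold higher in infected, CD4 T-like numbered 639 instead of 973 and Il18r1 turned from 0.66 to -0.35. Without its deepest cluster, erythroid-like cells had 1038 genes at least 2-fold higher in infected and 239 lower, and the maturation median (0.54), the dissociation stress median (-0.49 to 0.43), Rsad2 (-3.12 to 0.37) and Xpo7 (-3.34 to 0.22) turned. With genes left out that free RNA could set, genes at least 2-fold lower in infected, erythroid-like numbered 326 and the dissociation stress median there turned to 1.16.

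Small classes had fewer UMIs and fewer measured genes than B-like cells. The red pulp macrophage-like sums held 687649 saline and 466305 infected UMIs and allowed 5088 genes to be measured, against 11120 in B-like cells. Neutrophil-like sums held 207022 saline UMIs and allowed 3574.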

Other observations

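The 39 saline and 374 infected plasma-like cells lay in clusters C17 and C19 and were too few in saline for gene values. NK-like cells (263 saline and 32 infected, T2), gamma delta T-like cells (205 and 28) and plasmacytoid dendritic-like cells (48 and 31) were likewise too few in infected mice.

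Some values in the smaller classes stand outside the main comparisons. In infected monocyte-like cells transferrin (Trf) had a log2 ratio of -2.88, and the chromatin protein gene Hmgb2 stood at 672 and 214 CPM (-1.65). Neutrophil-like cells had the GTPase gene Ifi47 at 6.28, the chemokine Ccl5 at 6.01, the immediate early gene Fos at -2.36, the prostaglandin synthase Ptgs2 at -1.85 and Rgs2 at -3.24. In cDC2-like cells Iigp1 had a ratio of 9.17 and Cxcl10 7.51. In CD4 T-like cells the Tfh and naive list member Tcf7 stood at 499 and 334 CPM (-0.58, and -0.025 without T6.0 and T6.3), and in CD8 T-like cells the receptor chain Klrd1 at 272 and 304 CPM (0.16).

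Medians of interferon-stimulated genes in the added classes were 1.10 in Treg-like, 1.14 in cDC1-like, 1.49 in cDC2-like, 1.35 in monocyte-like and 1.43 in neutrophil-like cells. Proliferation genes had medians of 1.46 in cDC1-like, 1.36 in cDC2-like and 2.14 in neutrophil-like cells, and MHC class I genes 1.08 in cDC2-like cells.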
